A study of Mus musculus with 4 samples.

How the data were processed

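Gene expression was measured on 4 one-colour Agilent arrays, 1 for each of WT and Mkx-KO tissue at 10 and 4 weeks. Per the labels, total RNA was extracted with ISOGEN, and 0.1 ug of it was made into Cy3-labelled cRNA with a low input amplification kit. Per the file headers, all 4 arrays lay on 1 slide, and the values are spot intensity read with Agilent Feature Extraction 11.5.1.1. The processed signal used here is background-subtracted and spatially detrended on each array by that software and is on a linear scale. The same deposited scan data give the median pixel intensity of each spot and of its local background, and an error estimate of the processed signal. The deposited series table also holds intensity on a linear scale. Compared with the scan data, each of its columns equals the processed signal times 1 factor per array: 1.81 for WT and 2.08 for Mkx-KO at 10 weeks, and 1.64 and 1.54 at 4 weeks. The labels do not say how these factors were chosen, and the values are not centred per gene.

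Probes were named by matching the RefSeq accession in the array design to a RefSeq gene table of the mouse genome. The array design is annotated on mm9 and the gene table belongs to a later build, so no positions are given. Of 56605 probes, 32994 (58.3%) matched a gene and 23611 did not; these last were left out, since they carry no gene name to report. Of 29638 probes with a RefSeq mRNA accession, 299 found no match. The named probes stood for 22911 genes, 7899 of them with more than 1 probe, and the probe with the brightest mean over the arrays represented its gene. Spots of the same probe were averaged on the log2 scale, and the 60 to 77 spots per array that the scanner software marked as outliers were left out.

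Signals were log2 transformed and the 75th percentile of the non-control probes of each array was subtracted. A gene counted as measured in a comparison when the scanner software called its probe well above background on both arrays. Such a gene was called when its difference was at least 2-fold. Where a gene was well above background on 1 array of a pair only, the difference was bounded with the lowest level called well above background on the other array and written as at least N-fold. Technical errors of a difference combine the error estimates of the scanner software for both spots, with a median of 0.20 log2 units. They do not cover variation between mice. With 1 array per group no p-value was computed for a single pair.

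Before the data were examined, 34 gene lists were fixed, covering matrix, signalling and stress genes and markers of cell types. They had 551 memberships of 550 genes measured here, with 1 gene in more than 1 list. A list was scored over genes well above background on at least 2 of 4 arrays. Its median difference was compared with 10000 random lists drawn from the same 20 bins of mean expression, and it stood apart when it lay outside their central 95%. The percentile among the random lists describes these arrays and is not a test over mice.

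limma 3.58.1 in R 4.3.3 fitted genotype and age together over the 4 arrays, for 16795 genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment and an adjusted p of 0.05 as threshold. This leaves 1 residual degree of freedom. On simulated data with 50 changed genes at each size, the fit recovered 0 genes changed by 1 log2 unit, 0 changed by 2, 30 changed by 4 and 47 changed by 8, with 5 false calls. Random lists of 15 genes, tested on simulated differences, stood apart in 5.0% of draws with no shift and in 100% with a shift of 0.5 log2 units. The simulated genes varied independently and with less spread than the measured differences, whose standard deviations were 0.37 to 0.74. These shares need not hold for lists whose members move together. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

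Genes were named by a rule fixed beforehand. It takes Mkx, the 10 genes farthest apart in each direction for genotype at each age, the 10 in each direction with the largest smaller difference of both ages, the 8 in each direction for age in each genotype, the 3 largest bounds in each direction for genotype, up to 4 members of each list with the largest mean size of difference, and 16 matrix, bone and cartilage genes chosen in advance. Olfactory receptors and genes with only a clone or locus number were not named among those farthest apart. Other genes are said to be named after their values were seen.

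The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, centring on the median of probes above background on all arrays, the deposited scaled values, the mean over the probes of a gene, other background filters, fold thresholds of 1.5 and 3, a requirement that 2-fold differences also exceed 2 technical errors, list members at their bounds, and 5 further forms of the limma fit. The mean spot intensity planned for normexp is not among the columns used here, and the median spot intensity took its place. Added after the data were seen were leaving out probes in bright patches, leaving out nasal and related genes, leaving out each array in limma fits of 1 factor, genotype or age, and lists of olfactory, nasal gland, forebrain and ciliated cell genes, scored also over the members well above background on both arrays. Patches were windows of 8 by 8 spots with at least 20 usable spots and a median at least 0.5 log2 units from the other arrays. Control spots were used only to look at patches. No sample was left out, and the slide was not fitted as a block because there was 1 slide.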

Results

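RNA was measured in mouse tissue labelled PDL, the abbreviation of periodontal ligament, the connective tissue that ties a tooth root to its bony socket. Mice were wild type (WT) or knocked out for Mkx (Mkx-KO). Mkx encodes Mohawk homeobox, a transcription factor of tendon and ligament. The tissue came from mice of 10 or 4 weeks of age, which made 4 groups: WT and Mkx-KO at 10 weeks, and WT and Mkx-KO at 4 weeks. Each group had 1 array, so there were no biological replicates, and the labels do not say how many mice each preparation held. The differences are therefore descriptions of these 4 arrays, and their number limits the precision.

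Each array carried 62976 spots, of which 59305 were not controls and held 56605 different probes. The scanner software called 66.6% of these spots well above background for WT and 65.3% for Mkx-KO at 10 weeks. At 4 weeks the shares were 62.3% for WT and 61.8% for Mkx-KO. No spot was saturated. The median standard deviation between replicate spots of a probe lay between 0.0389 and 0.0425 log2 units over the arrays. Across 15504 genes well above background on all arrays, the correlation between arrays was 0.990 for WT and Mkx-KO at 10 weeks and 0.981 for WT and Mkx-KO at 4 weeks. It was lowest, 0.957, between WT at 10 weeks and Mkx-KO at 4 weeks; genes are not independent replicates. Levels are log2 signals relative to the 75th percentile of the array, and differences are log2 differences, Mkx-KO minus WT or 10 minus 4 weeks.

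Mkx RNA was lower in Mkx-KO at both ages. The brighter of its 2 probes (A_51_P519008) read a processed signal of 553 in WT and 108 in Mkx-KO at 10 weeks, a difference of -2.10 with a technical error of 0.21 from the scanner software. At 4 weeks it read 563 in WT and 193 in Mkx-KO, a difference of -1.65. These differences are between levels after the scaling of each array, not between the processed signals as read. On the scaled levels, Mkx-KO was at 23.3% of WT at 10 weeks and 31.8% at 4 weeks. The dimmer probe (A_66_P123656) gave -1.94 and -1.38, but only -0.57 and -0.62 after normexp background correction. All Mkx signals were well above background, and the place of the probes relative to the deleted part of the gene was not used here.

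**Figure D1:**
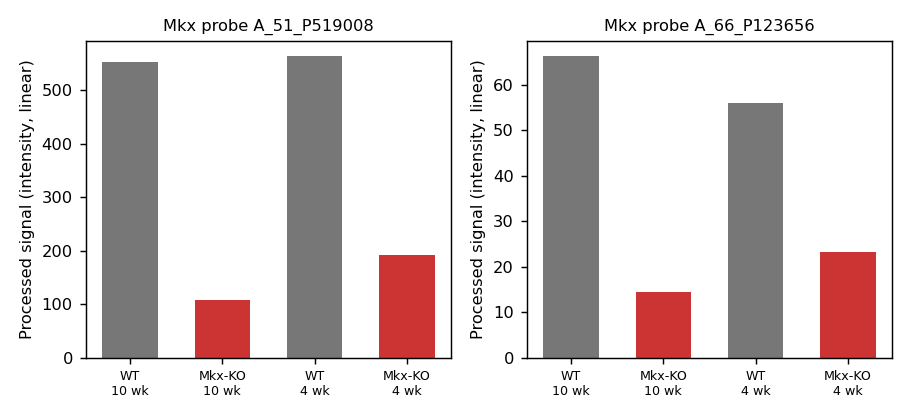
Processed signal (intensity, linear axis from 0) of the 2 Mkx probes on each of the 4 arrays, 1 bar per array, grey for WT and red for Mkx-KO. The brighter probe read 553 and 563 in WT against 108 and 193 in Mkx-KO.

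The comparison of Mkx-KO with WT at 10 weeks addressed which transcripts of the adult tissue differ in the knockout. Genes induced by interferon, the signal of antiviral defence, were the group most clearly lower in Mkx-KO. The chemokine genes Cxcl9 and Cxcl10, whose products draw T cells, differed by -5.73 and -3.84. The guanylate-binding gene Gbp2 differed by -2.77 and the antiviral gene Ifit1 by -2.36. Of 17 interferon response genes, 11 were at least 2-fold lower and none at least 2-fold higher. Their median was -1.13, below all 10000 random lists of the same expression level (percentile 0). Ifit1bl1 was well above background in WT only and was at least 18.6-fold lower in Mkx-KO.

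Bone and marrow transcripts were on the higher side in Mkx-KO at 10 weeks. Osteoclast markers, from the cells that resorb bone, had a median of 0.92, and all 14 were positive. Calcr, the calcitonin receptor gene, differed by 1.27, Slc9b2 by 1.15, and the cell fusion genes Dcstamp and Ocstamp by 1.07 each. Ibsp, the gene of bone sialoprotein, differed by 1.58 in an osteoblast and cementoblast list whose median was 0.16. B cell markers had a median of 1.16, with 7 of 13 at least 2-fold higher, including Ms4a1 at 1.43 and Mzb1 at 1.49. Neutrophil precursor genes had a median of 0.76 with Ctsg at 0.99 and Prtn3 at 1.14. Erythroid genes had a median of 0.65, with Car1 at 1.13 and Rhag at 1.05. Medians were smaller in the skeletal muscle list (0.38), the adipocyte list (0.31), the cell cycle list (0.25), the monocyte and macrophage list (0.22), the mitochondrial list (0.15) and the endothelial list (0.12), all above the central 95% of random lists.

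Epithelial transcripts were lower. The keratin genes Krt76, Krt4, Krt13 and Krt6a, typical of oral and gingival epithelium, differed by -2.39, -1.12, -1.04 and -0.96. The epithelial list had a median of -0.75, with 20 of 21 members negative. The odontoblast and ameloblast list, genes of the cells that make dentine and enamel, had a median of -0.32; Odam differed by -1.34 while Dspp differed by 1.0. Small leucine-rich proteoglycans, which bind collagen fibrils, had a median of -0.22, with the keratocan gene Kera at -1.90 and Podn at -0.41. Inflammatory chemokine genes had a median of -0.21 with Ccl2 at -1.31, T and natural killer cell markers -0.24 with Cd3g at -1.27, and Wnt genes -0.15 with Rspo3 at -0.94. The calls of the mitochondrial, endothelial and T cell lists were lost with normexp background correction, and that of the osteoblast list with quantile normalization.

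The main collagen genes and Postn differed little at 10 weeks. Col1a1, Col1a2 and Col3a1, which encode the main fibrillar collagens, differed by 0.14, 0.20 and 0.21. Postn, the periostin gene, differed by 0.05, Dcn, the decorin gene, by -0.26 and Col12a1 by 0.19. The tendon genes Scx and Tnmd differed by 0.71 and -0.28. Lox, which encodes the enzyme that cross-links collagen, was higher by 0.95, Tnc, the tenascin C gene, by 0.52 and the dermatopontin gene Dpt by 1.07. The lists of tendon factors (median 0.04), fibrillar collagens (0.14), collagen processing (0.09), elastic fibres (-0.03), matricellular proteins (0.07), proteases (0.08) and TGF-beta signalling (-0.00) lay within the central 95% of random lists. So did the lists of immediate early genes (-0.04), endoplasmic reticulum chaperones (0.08), sex-linked transcripts (0.34), chondrocyte (0.07), mast cell (-0.03), smooth muscle (-0.07), Schwann cell (-0.03), salivary gland (-0.08) and general fibroblast (-0.01) genes.

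Among all 16457 genes well above background on both arrays at 10 weeks, 396 (2.41%) were at least 2-fold apart, 171 higher and 225 lower in Mkx-KO. Among the 10 genes farthest on the higher side, the prolactin gene Prl differed by 3.63, the secretoglobin genes Scgb1b27, Scgb2b27, Scgb1b3 and Scgb2b20 by 3.37, 3.12, 2.68 and 2.64, and the kallikrein gene Klk1b9 by 2.86. Gad1, which encodes the enzyme that makes the transmitter GABA, differed by 2.66 and Cpne6 by 2.75. Fam205a2 (4.18) and Serpina3f (3.03) were also among the 10, but their other probes went down to -0.02 and -0.52. On the lower side were Bpifb6 (-3.61), Bpifb3 (-3.52), Gpx6 (-3.39), Scgb1c1 (-3.27), Chil4 (-3.23), the neuropeptide gene Vip (-3.18), Chil6 (-2.87) and Vmo1 (-2.84), several of them secreted in the nasal lining. Genes well above background on 1 array only were bounded: Kcnd2, Klk1b16 and Smco2 were at least 5.98-fold, 4.88-fold and 4.15-fold higher in Mkx-KO, and Srd5a2 and Rgr at least 5.02-fold and 4.91-fold lower. The 3 probes of Rgr ranged from -2.93 to -0.85. Near-identical sequences within the Scgb, Klk1b and Bpif families leave open which member a probe reads.

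The comparison of Mkx-KO with WT at 4 weeks addressed the tissue of young mice. The widest differences were in transcripts of the nose. Omp, the olfactory marker protein gene, stood at 4.87 in WT and -3.26 in Mkx-KO, a difference of -8.13. The olfactory G protein gene Gng13 differed by -6.30. Genes of secreted odorant carriers were as far apart: Mup4 -9.74, Lcn11 -7.63 and Obp1a -7.02. So were Wfdc18 (-8.29), the nasal enzyme genes Cyp2a4 (-7.01) and Cyp2a5 (-6.82) and the secretory granule gene Chga (-6.80). Bpifb9b, Mup20 and Mup21 were well above background in WT only and at least 11612-fold, 583-fold and 459-fold lower in Mkx-KO. Each of these genes stood above the 75th percentile of each of the other 3 arrays. Members of the Mup, Cyp2a and Bpif families are hard to tell apart by probe.

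Lists of olfactory, nasal gland, forebrain and ciliated cell genes, written after these values were seen, gave the following medians at 4 weeks. Olfactory sensory neuron genes had a median of -3.63, with 15 of 19 at least 2-fold lower. Of these genes 9 were not well above background in Mkx-KO, and with those at their bounds the median was -3.44. The other 10 had a median of -1.59. Nasal gland genes had a median of -7.13, or -5.59 with 8 members at their bounds, and the other 8 had a median of -5.03. Forebrain inhibitory neuron genes had a median of -3.82, with 11 of 16 at least 2-fold lower, or -2.88 with 6 at their bounds. The 10 well above background on both arrays had a median of -0.66 but were split. Gad1, Slc32a1, Synpr, Syt1 and Reln differed by -3.86, -4.54, -2.69, -4.58 and -1.21. The regulators Dlx1, Dlx2, Dlx5, Dlx6 and Lhx6 differed by -0.10, 0.21, 0.47, 0.02 and 0.18. Slc32a1, Syt1, Reln and the regulators are named after their values were seen. Ciliated cell genes had a median of -0.64, but 7 of 14 lacked a measured difference, 3 being well above background in WT only and 4 on neither array; the other 7 had a median of -0.62. At 10 weeks the olfactory median was -0.20 and the nasal gland median -0.21, with 3 members at least 2-fold higher and 7 lower.

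**Figure D2:**
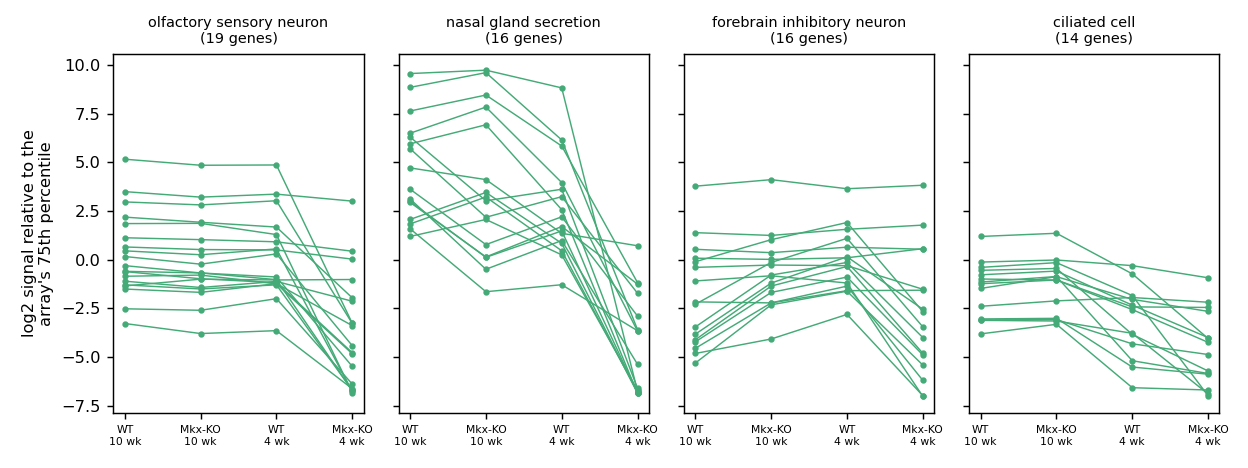
Levels (log2 signal relative to the 75th percentile of the array) of the genes in the olfactory, nasal gland, forebrain and ciliated cell lists on each array, 1 line per gene. Most olfactory and nasal gland genes dropped on the Mkx-KO array of 4 weeks, where Omp stood at -3.26 against 4.87 in WT, while forebrain genes such as Gad1 were highest in WT at 4 weeks (-0.14).

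Muscle and marrow transcripts were lower in Mkx-KO at 4 weeks. The skeletal muscle list had a median of -1.17, with 13 of 18 genes at least 2-fold lower; Tcap, Ckm, Acta1 and Myh2, all genes of the contractile apparatus and its energy supply, differed by -1.95, -1.69, -1.56 and -1.14. Neutrophil precursor genes had a median of -1.17, with Camp at -1.63, Ctsg at -1.47 and Ngp at -1.29. The salivary gland list had a median of -1.54, with Pip at -4.62 and with Dcpp2 and Bpifa2 at least 14.4-fold and 13.7-fold lower. Mast cell genes had a median of -0.59, erythroid genes -0.37, T and natural killer cell genes -0.31 (Gzma -1.45, Nkg7 -1.24) and adipocyte genes -0.29 (Adipoq -1.77). Interferon genes had a median of -0.62, with 3 of 17 at least 2-fold lower, among them Ifit2 (-1.20) and Ifit3 (-1.06). Smaller medians below the random lists belonged to osteoblast and cementoblast genes (-0.14; Ibsp -1.13, Mepe -1.5), Schwann cell genes (-0.13), monocyte genes (-0.11) and small leucine-rich proteoglycans (-0.11; Kera -1.16).

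Genes of matrix assembly and protein folding were higher in Mkx-KO at 4 weeks. Collagen processing genes had a median of 0.37, with Lox at 0.88 and the prolyl hydroxylase gene P4ha2 at 0.62. Fibrillar collagens had a median of 0.32, with Col5a3, Col5a1, Col8a1 and Col15a1 at 0.80, 0.79, 0.59 and 0.54. Endoplasmic reticulum chaperones had a median of 0.40, with the stress regulator Creb3l1 at 0.84 and Manf, Pdia4 and Pdia6 at 0.78, 0.68 and 0.61. The elastic fibre list had a median of 0.27, with the fibrillin gene Fbn2 at 1.27. Matrix proteases had a median of 0.21 with Adamts4 at 1.21, and immediate early genes 0.35 with Fosl1 at 1.13. The main collagens again differed little: Col1a1 by 0.05, Col1a2 by -0.03 and Col3a1 by -0.02, where the Col1a1 probe lay in a brighter patch of the Mkx-KO array. Postn differed by 0.05, Scx by 0.30, Tnmd by -0.19 and Fmod by 0.43. In the smooth muscle list, which did not stand apart with 8 members positive and 5 negative, Tagln differed by 1.22, Des by -1.57 and Acta2 by 1.63, the highest of its 3 probes, which began at 0.32.

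Epithelial genes were on the higher side at 4 weeks, with a median of 0.59 and 20 of 21 members positive; Krt4, Krt13 and Krt6a differed by 0.99, 0.97 and 0.97. B cell markers had a median of 0.20 with 3 genes at least 2-fold higher, such as Ms4a1 (1.56), and 3 lower, such as Igll1 (-2.23) and Vpreb1 (-1.78), which mark B cell precursors. Sex-linked transcripts had a median of 0.49, above the random lists, with 4 of 5 members positive and 1 negative. All 5 were well above background on both arrays. The list mixes Xist with Y-linked genes, so its median is no measure of sex, which the labels do not give. The Y-linked genes Eif2s3y and Kdm5d differed by 0.74 and 0.49 at 4 weeks and by 0.36 and 0.32 at 10 weeks. A second Kdm5d probe gave -0.06 at 10 weeks. At that age 4 of 5 members were also positive and 1 negative. A difference between the preparations in the sex of the mice was not tested. Lists within the central 95% of random lists were tendon factors (0.03), matricellular proteins (0.04), TGF-beta (0.11), Wnt (0.14), inflammatory (0.13), cell cycle (0.14), mitochondrial (0.08), osteoclast (0.00), chondrocyte (0.11), odontoblast and ameloblast (0.17), endothelium (0.01), smooth muscle (0.18) and general fibroblast (0.05) genes. The calls at 4 weeks of the small leucine-rich proteoglycan, B cell, T cell, osteoblast, Schwann cell and adipocyte lists were each lost under at least 1 alternative processing.

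Of 15686 genes well above background on both arrays at 4 weeks, 593 (3.78%) were at least 2-fold apart, 74 higher and 519 lower in Mkx-KO. The acute phase gene Saa3 led the higher side at 6.17, followed by Cox6b2 (2.69), the retinoic acid enzyme gene Cyp26a1 (2.21), Col26a1 (1.99), the relaxin gene Rln1 (1.82), Hhip (1.79), the somatostatin receptor gene Sstr1 (1.78) and Ephb4 (1.67). A second probe gave 0.67 for Col26a1 and 0.72 for Ephb4. Timm21 (1.64) lay in the brighter patch. The enamel gene Amelx differed by -6.66 and Enam was at least 18.3-fold lower in Mkx-KO, while Ambn differed by 0.13 and Amtn by 1.01. Another 382 genes well above background in WT only were at least 2-fold lower by their bound, against 23 higher by their bound. The 3 largest bounds on the higher side, Wnt9b, Usp9y and Ccdc70, at least 82.8-fold, 32.6-fold and 26.5-fold, all lay in the brighter patch.

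Local brightness touched a few named genes. Some windows of the Mkx-KO array of 4 weeks read up to 1.23 above the other arrays, and some of the WT array of 4 weeks up to 1.37. These patches held 100 and 214 spots, with probes of 43 and 84 genes. Ccdc70, Col1a1, Timm21, Usp9y, Uty and Wnt9b had probes in the Mkx-KO patch, and Cyp2c23 and Mpeg1 in the WT patch. The search for such patches was chosen after the values were seen.

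**Figure D3:**
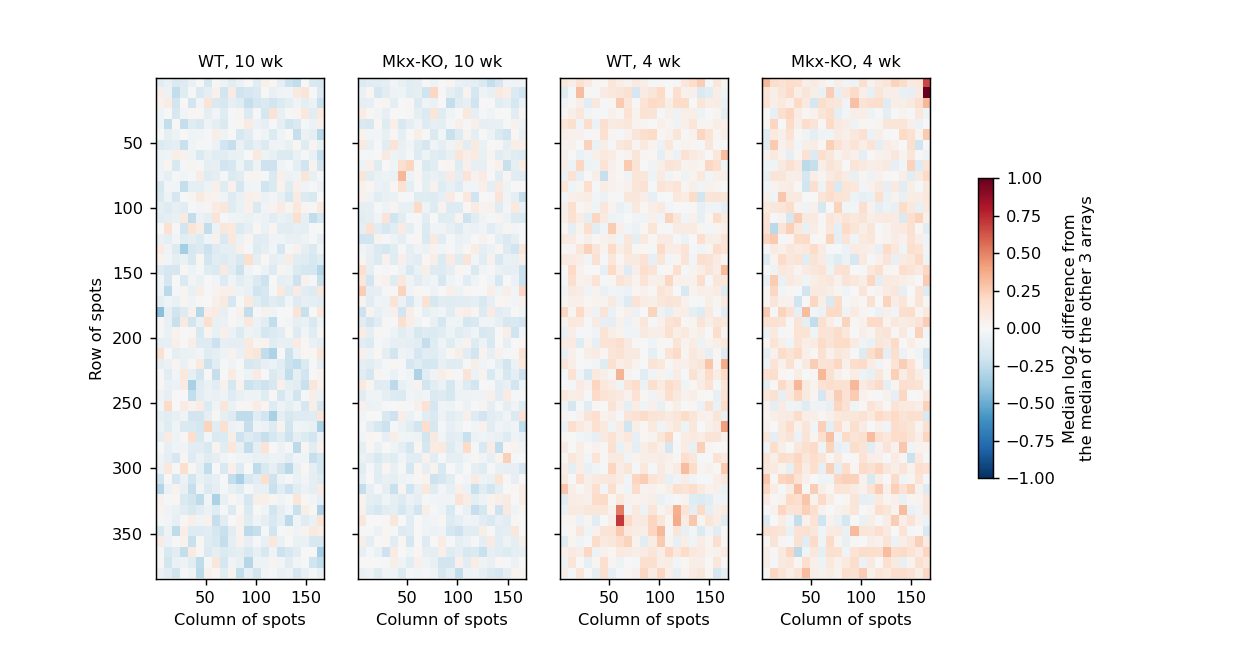
Median log2 difference of blocks of 8 by 8 spots from the median of the other 3 arrays, by row and column of spots, for each of the 4 arrays. Bright blocks stand out on both arrays of 4 weeks, where windows reached 1.37 in WT and 1.23 in Mkx-KO, and none at 10 weeks.

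The comparisons at both ages together addressed which genotype differences recur. Some genes of B cells were at least 2-fold higher in Mkx-KO at 10 and at 4 weeks: Ms4a1 (1.43 and 1.56), Tnfrsf13c (1.61 and 1.42), Spib (1.24 and 1.12) and Niban3 (1.33 and 1.19). The lowest probe of Tnfrsf13c gave 0.55 at 10 weeks. The B cell list as a whole was split at 4 weeks, with 7 members positive, 6 negative and a mean of -0.19. Sstr1 was also higher at both ages (1.82 and 1.78), as was the secreted matrix gene Spon2 (1.5 and 1.07). Genes lower at both ages included the nasal secretion genes Bpifb3 (-3.52 and -4.96), Vmo1 (-2.84 and -5.10), Bpifb4 (-2.80 and -2.96) and Chil4 (-3.23 and -2.36), then Mkx, Myl10 (-1.46 and -1.44), Abca4 (-1.35 and -1.25), the interferon gene Ifit2 (-1.24 and -1.20), Kera (-1.90 and -1.16) and Spink12 (-1.5 and -1.14). Just under 2-fold at 1 age or both were the B cell gene Fcrla (1.28 at 10 weeks, 1.99-fold at 4 weeks), Lox (0.95 and 0.88), Dpt (1.07 and 0.94) and the Wnt agonist gene Rspo3 (-0.94 and -1.13).

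Of 15504 genes well above background on all arrays, 25 were at least 2-fold apart the same way at both ages, 8 higher and 17 lower, where independence of the ages would give 6.65. A further 61 were apart in opposite ways, 58 of them higher at 10 and lower at 4 weeks, where independence would give 4.87. The correlation of the genotype differences of both ages across genes was -0.16, and 48.1% of genes had the same sign. Of 34 lists, 18 stood apart from random lists at 10 weeks (11 higher, 7 lower) and 21 at 4 weeks (9 higher, 12 lower). By construction 1.7 would do so if list members varied independently of each other. Only 4 stood on the same side at both ages: interferon response, small leucine-rich proteoglycans and T and natural killer cells lower, and B cells higher. Of these, interferon genes alone kept their call at both ages under all 9 list alternatives. Among the 9, centring and the deposited values shift all genes of an array alike and could not change a call. Small leucine-rich proteoglycans lost it at 4 weeks with quantile normalization, T cells at 10 weeks with normexp and at 4 weeks with no background filter, and B cells at 4 weeks with either of the latter. The skeletal muscle, neutrophil, erythroid, adipocyte, monocyte, osteoblast and epithelial lists stood on opposite sides.

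**Figure D4:**
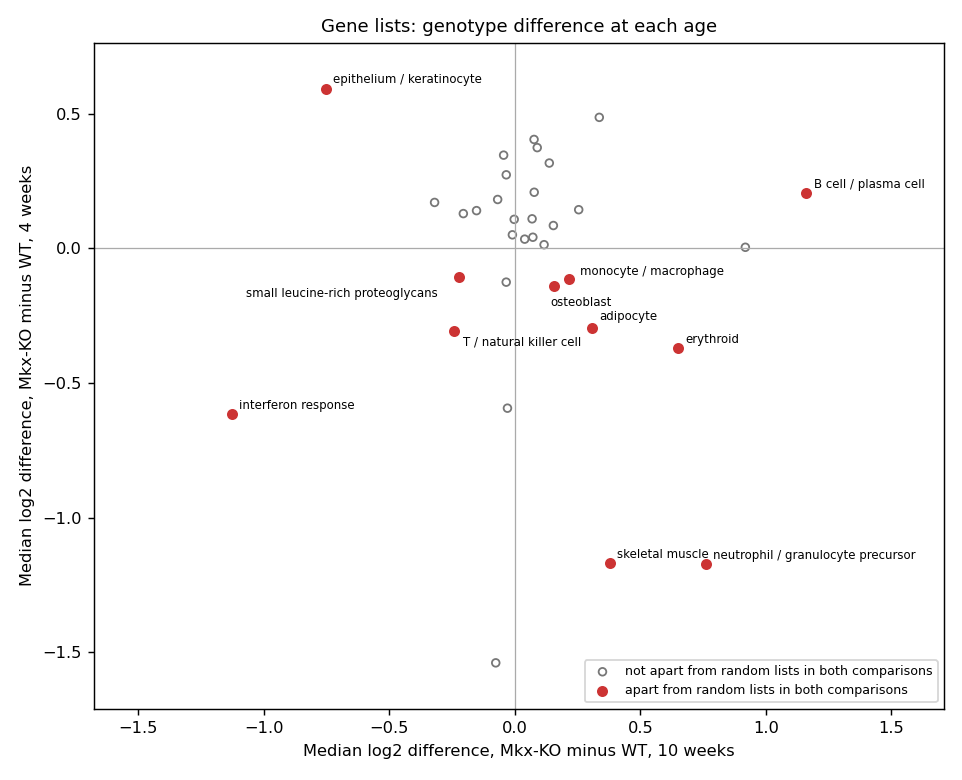
Median log2 difference, Mkx-KO minus WT, of each of 34 gene lists at 10 weeks (horizontal) and at 4 weeks (vertical), 1 point per list; red points stood apart from matched random lists at both ages. Interferon response genes were lower at both ages (-1.13 and -0.62), while skeletal muscle genes were higher at 10 weeks (0.38) and lower at 4 weeks (-1.17).

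The age comparison in WT addressed how the tissue of 10 weeks differs from that of 4 weeks. Genes of tooth formation were lower at 10 weeks. Dspp, the dentine sialophosphoprotein gene, differed by -3.84, Amtn by -2.69 and Ambn by -2.58, and the enamel protease gene Mmp20 was at least 18.5-fold lower. The odontoblast and ameloblast list had a median of -1.63. Osteoclast genes had a median of -1.33, with Ocstamp at -1.90 and Mmp9 at -1.68. Collagen processing genes had a median of -0.49, with Lox at -1.5, P3h1 at -1.21 and Loxl4 at -1.06. B cell genes had a median of -0.59. Among single genes, Spon2 differed by -4.08, Adamts4 by -2.72, Scx by -1.22, Tnmd by -0.81 and Bglap, the osteocalcin gene with near-identical copies, by -1.31.

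Interferon and epithelial genes were higher at 10 weeks in WT. The interferon list had a median of 1.51, with 12 of 17 at least 2-fold higher and 1 lower; Cxcl9 differed by 6.29, Cxcl10 by 3.52 and Ifit1 by 2.92. Epithelial genes had a median of 1.09, with Krt76 at 1.90, Dsg3 at 1.88 and Krt6a at 1.52. Salivary gland genes had a median of 0.86 with the acinar regulator Bhlha15 at 2.78. Smaller medians were found for adipocyte (0.50), T and natural killer cell (0.37), skeletal muscle (0.33), inflammatory (0.31), neutrophil (0.29) and general fibroblast (0.12) genes. The T cell call was lost with the mean over the probes of a gene. Cxcl13 was at least 5.22-fold higher, and the lipid enzyme gene Mogat1 differed by 4.23. The genes farthest apart also included Bpifa6 (5.74), Aadacl4fm1 (5.23), Pnliprp1 (4.49), Cyp2b9 (4.24), Aqp8 (4.21) and Dnase1 (4.18) on the higher side, and Unc93a2 (-4.45), Scgb1b19 (-4.18), Synpr (-3.97), Cpne6 (-3.76) and Scgb1b2 (-3.65) on the lower. Cyp2c23 (-4.41) lay in the WT patch. In all, 1423 of 16102 genes (8.84%) were at least 2-fold apart, 806 higher and 617 lower at 10 weeks.

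Lists that did not stand apart for age in WT were tendon factors (0.09), fibrillar collagens (-0.33), small leucine-rich proteoglycans (0.02), matricellular (-0.07), elastic fibre (-0.16), protease (-0.11), TGF-beta (-0.10), Wnt (-0.05), immediate early (0.06), cell cycle (-0.17), chaperone (-0.34), mitochondrial (-0.32), sex-linked (0.23), osteoblast (-0.35), chondrocyte (0.07), erythroid (-0.19), monocyte (-0.13), mast cell (-0.12), endothelial (-0.27), smooth muscle (-0.07) and Schwann cell (-0.06) genes. Some of these medians were larger in size than those of lists that stood apart. Random lists could be centred on the negative side for age, at -0.21 for those matched to the fibrillar collagens. Small age differences changed sign with the scaling. With the deposited scaled values the median of all genes moved by 0.36 in WT and 0.29 in Mkx-KO, and 1536 genes were then at least 2-fold higher and 317 lower in WT, and 1535 higher and 262 lower in Mkx-KO.

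The age comparison in Mkx-KO set 10 against 4 weeks within the knockout. Most tooth genes and several matrix lists were lower at 10 weeks. Dspp differed by -3.01, Mmp20 by -3.78, Amtn by -3.57 and Ambn by -3.36, in a list with a median of -1.09, 5 members at least 2-fold lower and 2 higher. Amelx, of the same list, differed by 4.71. Collagen processing genes had a median of -0.79 with Lox at -1.43. Chaperones had a median of -0.72 with Creb3l1 at -1.59, fibrillar collagens -0.49 with Col5a1 at -1.25, elastic fibre genes -0.47 with Fbn2 at -2.82, proteases -0.43 with Adamts4 at -3.03, and Wnt genes -0.36 with Nkd1 at -2.44. Col26a1 (-5.57), Saa3 (-4.53), the progenitor gene Dlk1 (-4.17), Spon2 (-3.65) and Crtac1 (-3.08) led the lower side, though a second Col26a1 probe gave only -1.80. Col1a1 differed by -0.12 and Postn by -0.11.

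On the higher side at 10 weeks in Mkx-KO were the transcripts that were dim on the 4-week array. Mup4 differed by 13.20, Wfdc18 by 10.08, Obp1a by 9.63, Dnase1 by 8.85, Omp by 8.11, Cyp2a4 by 7.56 and Cyp2a5 by 7.39. Salivary gland genes had a median of 2.87, or 2.12 with 4 members at their bounds, neutrophil genes 2.14 with 13 of 14 at least 2-fold higher, and skeletal muscle genes 1.90 with 16 of 18. Interferon genes had a median of 0.69 and erythroid genes 0.64. Then came adipocyte (0.58), T and natural killer cell (0.52), mast cell (0.50), general fibroblast (0.26), Schwann cell (0.18), monocyte (0.12) and matricellular (0.06) genes. Of the matricellular genes 8 were positive and 6 negative, and the list stood apart from a random range of -0.49 to -0.01. Its member Ccn2, the connective tissue growth factor gene, differed by 2.94. In all, 1580 of 15669 genes (10.1%) were at least 2-fold apart, 979 higher and 601 lower. Lists within the random range were tendon factors (-0.17), small leucine-rich proteoglycans (-0.01), TGF-beta (-0.12), inflammatory (-0.19), immediate early (-0.39), cell cycle (0.05), mitochondrial (-0.32), sex-linked (0.19), osteoblast (-0.34), osteoclast (-0.34), chondrocyte (-0.23), epithelial (-0.27), B cell (0.28), endothelial (-0.27) and smooth muscle (-0.17) genes. The calls of the Wnt, elastic fibre, protease, matricellular and Schwann cell lists were each lost under at least 1 alternative.

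Age differences recurred across genotypes more often than genotype differences across ages. Lox, P3h1, Loxl4, Dspp and Spon2 were lower, and Mogat1 (4.23 and 4.04), Ifit1 (2.92 and 1.45) and Bhlha15 (2.78 and 3.87) higher at 10 weeks in WT and in Mkx-KO. Of 15504 genes, 540 were at least 2-fold apart the same way in both genotypes (340 higher, 200 lower) and 78 in opposite ways, where independence would give 63.4 and 60.5. The correlation of the age differences across genes was 0.52. Of the lists, 9 stood on the same side: interferon, skeletal muscle, neutrophil, T and natural killer cell, adipocyte, salivary gland and general fibroblast genes higher, and collagen processing and odontoblast and ameloblast genes lower at 10 weeks. All but T and natural killer cells kept both calls under all 9 list alternatives, of which centring and the deposited values could not change a call.

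**Figure D5:**
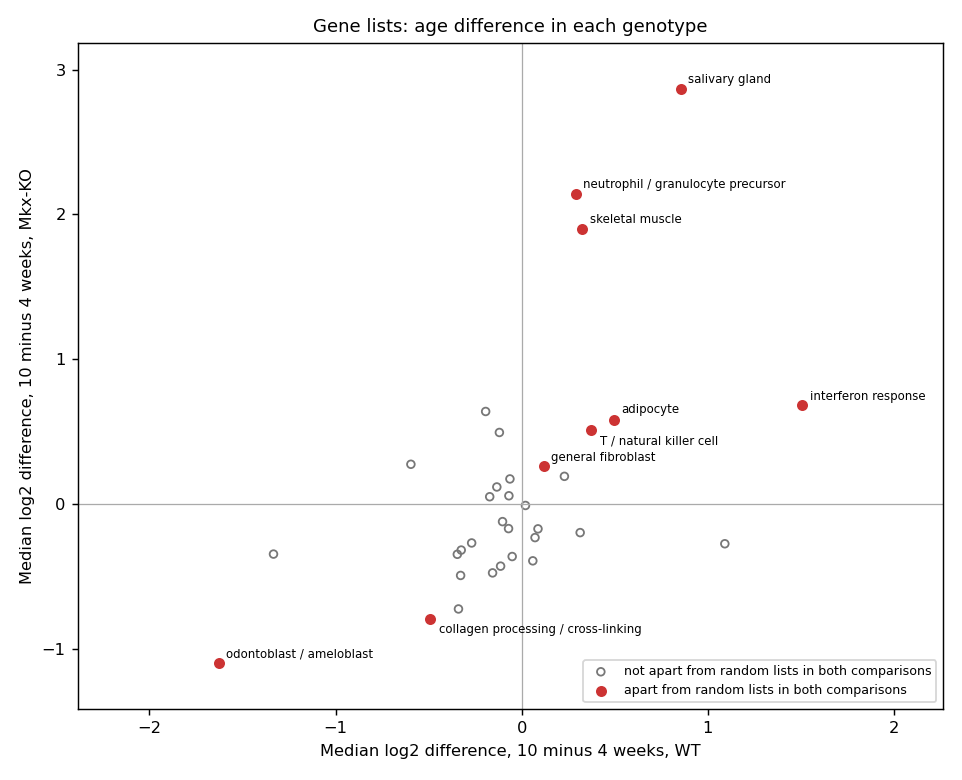
Median log2 difference, 10 minus 4 weeks, of each of 34 gene lists in WT (horizontal) and Mkx-KO (vertical), 1 point per list; red points stood apart from matched random lists in both genotypes. Odontoblast and ameloblast genes were lower at 10 weeks in both (-1.63 and -1.09), and interferon genes higher (1.51 and 0.69).

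A model over all 4 arrays asked whether genotype or age shifted a gene by a like amount in both pairs. limma, with 16795 genes and 1 residual degree of freedom, called 0 genes for genotype and 0 for age at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 455 genes for genotype and 4074 for age, where chance alone gives 840. The smallest adjusted p was 1.0 for genotype and 0.176 for age. With normexp background correction limma called 31 genes for age, and without genotype as a term 5.

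Some members of the B cell (4 of 13) and interferon lists (5 of 17) for genotype, and of the tooth list (5 of 9) for age, passed this test within the lists fixed beforehand. Adjusted over the list alone, limma called 10 genes in 3 lists for genotype and 32 genes in 8 lists for age, against 0 of each over all genes. Each list was adjusted separately, so 1.7 of the 34 would hold a call by chance. For genotype these included Ms4a1 (1.5), Cd79a (1.05) and Cd79b (1.14) of the B cell list, with adjusted p from 0.0242 to 0.0304. The interferon list gave Ifit2 (-1.22), Ifit3 (-1.28), Isg15 (-0.84), Oas1a (-0.77) and Irf7 (-0.93), with adjusted p from 0.0477 to 0.0495. The tendon list gave Mkx itself (-1.88, adjusted p 0.0462). For age, Dspp (-3.43), Ambn (-2.97), Amtn (-3.13) and Klk4 (-1.12) had adjusted p from 0.00558 to 0.00702 over the tooth genes well above background on all 4 arrays, which leaves out Mmp20, under it on 1. Collagen processing gave Lox (-1.46), P3h1 (-1.20), Loxl4 (-1.04), Plod2 (-0.82) and Adamts14 (-1.04), with adjusted p from 0.038 to 0.0493. The chondrocyte list gave 6 genes including Sox5 (1.18) and Col9a2 (-2.10), the salivary list 5 with Bhlha15 (3.32), the interferon list 4, the mast cell list 4, and the protease list Adamts4 (-2.87). Of the 5 salivary genes 1 was not well above background on 1 array. The inflammatory list gave Cxcl13, not well above background on 2 arrays, and Il33 (1.27), which no longer passed over the members that were on all 4 (adjusted p 0.065). Each estimate is the mean of both pairs of arrays. The spread behind its p comes from the disagreement between the pairs, not from variation between mice. A low p therefore says that both pairs differed alike, which a difference shared by the preparations would also give. Cd79b, Isg15, Oas1a, Irf7, Klk4, Plod2 and Adamts14 are named after their values were seen.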

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

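The tests of explanations reported here, with the olfactory, nasal gland, forebrain, ciliated cell and olfactory receptor lists, were chosen only after the result each bears on was seen. The differences in genotype effect between ages were not tested, since 4 arrays in 4 groups leave no residual degree of freedom for an interaction.

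Marrow, muscle and epithelial genes lay on opposite sides of WT at the ages, which is what singled them out. The gap between the genotype difference at 10 weeks and that at 4 weeks was 1.93 for neutrophil genes, 1.55 for skeletal muscle, 1.02 for erythroid, 0.60 for adipocyte, 0.33 for monocyte and macrophage and 0.30 for osteoblast genes, all higher in Mkx-KO at 10 weeks and lower at 4 weeks. For epithelial genes it was -1.35, lower at 10 weeks and higher at 4 weeks.

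Single genes were also at least 2-fold apart in opposite directions at the ages. The gap was 8.97 for the lipocalin gene Lcn11, 6.52 for the GABA enzyme gene Gad1, 5.44 for Fam205a2, whose probes disagreed, 5.31 for Synpr, 4.60 for Scgb2b20, 3.10 for Unc93a2, 2.96 for the adipocyte hormone gene Adipoq, 2.70 for the bone sialoprotein gene Ibsp and 2.37 for the neutrophil protease gene Prtn3. Saa3, an acute phase gene, had a gap of -7.77, being lower in Mkx-KO at 10 weeks (-1.60) and higher at 4 weeks (6.17).

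A few control spots for external RNA, which no comparison uses, were bright within the patches. The brightest such spot in the WT patch at 4 weeks stood at -0.18, against an array median of -6.62 for these controls, and in the Mkx-KO patch at -0.23 against -6.75. Most were not: the median of the control spots in the patches was -6.70 in WT and -6.63 in Mkx-KO, and -6.85 and -6.66 for the same spots on the other arrays. In the patches 2 of 9 and 4 of 9 control spots were at least 2-fold above the other arrays, against 4.33% and 4.04% of them on the whole arrays.

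Olfactory genes were low on the Mkx-KO array of 4 weeks alone, and so were many nasal gland genes. At 10 weeks both list medians were also below the random lists, but by far less. Of 16 nasal gland genes, 7 were at least 2-fold lower and 3 higher in Mkx-KO at 10 weeks. The Bpifb9b probe stood at 9.56, 9.74 and 8.83 on the other arrays and was not well above background on this one, where the lowest level so called was -4.68; Mup4 stood at 8.85, 9.61, 6.15 and -3.59, and Omp at 5.16, 4.85, 4.87 and -3.26. For olfactory genes as a set the tables argue against an effect of Mkx loss of the same size at both ages. Both lists were written because such genes were low at 4 weeks, so only their values at 10 weeks were free to differ. The rule of this test was also rewritten. The nasal gland median, with its spread at 10 weeks, did not clear the limit of the first form, so no conclusion is drawn for that list. The olfactory median was -0.20 at 10 weeks (standard deviation 0.20) and -3.44 at 4 weeks with members at their bounds (2.62 without bounds), and the nasal gland median -0.21 (2.09) and -5.59 (3.53 without bounds). Over the members well above background on both arrays, the medians at 4 weeks were -1.59 and -5.03. The nasal gland list was split at 10 weeks. The 7 genes at least 2-fold lower there, among them Bpifb4 (-2.80 and -2.96) and Chil4 (-3.23 and -2.36), were also at least 2-fold lower at 4 weeks. The other members lay between -0.60 and 1.39 at 10 weeks, so the median of -0.21 describes neither group. Scaling or background correction as the whole difference is argued against by the medians at 4 weeks under other processing. They shrank most with normexp, from -3.63 to -1.37 for olfactory and from -7.13 to -3.75 for nasal gland genes. Nasal tissue in the other 3 preparations, with little in this one, is a candidate explanation that the data leave undecided. Of its 19 olfactory genes 1 (Ebf1) is also in the B cell list and of the nasal gland genes 0 are in another list, and the labels name no sort or gate.

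The test of nasal tissue had a history that limits it. Its first form asked whether olfactory receptor (Olfr) genes, not used to find the pattern, were lower in Mkx-KO at 4 weeks, and a median inside the random range was to count against the explanation. The 158 Olfr genes well above background on at least 2 of 4 arrays had a median of -0.15, at percentile 37.4 of a random range from -0.26 to -0.05, so that form went against nasal tissue. At 4 weeks 60 of them were not well above background on both arrays, and the other 98 had a median of -0.02 in a random range from -0.13 to 0.05. Only after that value was seen was it argued that Olfr genes exclude nothing near the floor: their median level in WT at 4 weeks was -3.79, and the lowest level called well above background there was -4.53. Ciliated cell genes, whose median of -0.64 (-0.40 with normexp) was already known and lay below the random range of -0.47 to 0.15, were added at the same time, and only 7 of their 14 members were well above background on both arrays at 4 weeks (median -0.62), so nasal tissue may or may not be the source. A genotype effect that depends on age was not tested and stays open.

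Interferon response genes were lower in Mkx-KO at both ages. A high response on the WT array of 10 weeks alone is argued against by the median of -0.62 at 4 weeks, where that array is not used and the random range was -0.11 to 0.18. A fall of T and natural killer cells as large as that of interferon genes at 10 weeks is argued against by their median of -0.24. Its standard deviation was 0.48, against a median of -1.13 for interferon genes. These genes can be induced in other cells, so the comparison cannot decide on a smaller loss of T and natural killer cells. Less olfactory tissue as the whole difference at 10 weeks is argued against by the olfactory median of -0.20. Less nasal gland tissue at 10 weeks could account for it or not, since the members behind the median of -0.21 spread with a standard deviation of 2.09. Less olfactory tissue at 4 weeks also stays open: the olfactory median of -3.63 (standard deviation 2.62) lay below the interferon median, but the list was written because such genes were low there, so it could hardly have come out otherwise. A lower interferon response without Mkx is one hypothesis, and a difference in exposure or in mice between the preparations, 1 per group, was not tested.

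Some B cell genes were higher in Mkx-KO at both ages, but at 4 weeks the list was split, 7 positive and 6 negative with a mean of -0.19, and lost its call under 2 of 9 alternatives. Cd79b stood at 1.1 in WT and 2.45 in Mkx-KO at 10 weeks and at 1.89 and 2.83 at 4 weeks, and Ms4a1 at -0.44, 1.0, 0.43 and 1.99. More bone marrow in the Mkx-KO preparation could go with this at 10 weeks, where neutrophil genes had a median of 0.76 and erythroid genes 0.65, with Camp at 6.30 in WT and 7.04 in Mkx-KO and Hbb-b2 at 6.45 and 7.16. At 4 weeks the tables argue against it, with medians of -1.17 and -0.37. More lymphoid tissue of mixed T and B cells is argued against, though weakly, by T and natural killer cell medians of -0.24 and -0.31. Under the alternatives these medians rose as far as -0.01 and -0.12. The call was lost at 10 weeks with normexp and at 4 weeks with no background filter. The list also mixes T cell with natural killer cell genes. Lymphoid tissue rich in B cells, and an age-independent genotype effect on B cells, stay open and were not tested.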

How the results depend on the processing

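The alternatives of the normalization, filters, thresholds and limma fit were chosen before the data were examined; leaving out bright patches, nasal genes or single arrays was chosen after. No list median that stood apart and no named gene at least 2-fold apart changed sign under the alternatives run for it. Of 65 list medians that did not stand apart, 37 changed sign under at least 1.

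B cell and interferon list medians for genotype and both Mkx probes kept their sign, and interferon genes stood apart in every comparison under all 9 list alternatives. All 17 interferon genes were well above background on all arrays and none lay in a patch. The filters, bounds and patches therefore could not change their median, and centring and the deposited values could not change a call. Their median lay between -1.18 and -0.90 at 10 weeks and between -0.62 and -0.37 at 4 weeks. The brighter Mkx probe stayed more than 2-fold lower. The dimmer probe fell to -0.57 at 10 and -0.62 at 4 weeks with normexp; its input signal and its offset changed together, and the cause was not tested.

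Counts of genes at least 2-fold apart are given for genotype at 10 weeks, at 4 weeks, age in WT, age in Mkx-KO and genotype the same way at both ages, against 396, 593, 1423, 1580 and 25. Normexp gave 150, 259, 705, 814 and 8. No background filter gave 1384, 2071, 2919, 3445 and 150, since it adds genes near the floor. A threshold of 1.5-fold gave 1468, 1546, 3753, 4298 and 113, and 3-fold 86, 246, 491, 569 and 6, by construction. The larger side changed with 1.5-fold for genotype at 10 weeks (745 higher, 723 lower), age in WT (1691 and 2062) and age in Mkx-KO (1876 and 2422), and with no filter for genotype at 10 weeks (752 and 632). Quantile normalization, centring, the deposited scaled values, the mean over probes, the filter on all 4 arrays, and leaving out patches or nasal genes kept each count run within 1.5 times. The count for both ages already uses the filter on all 4 arrays, so that filter was run for the other counts only. Requiring 2 technical errors on top of 2-fold removed no gene and so tests nothing. Without patches the counts were 395, 584, 1410, 1576 and 25, and without nasal and related genes 361, 553, 1335, 1521 and 21.

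limma called 0 genes for genotype under all alternatives chosen beforehand. For age it called 31 with normexp and 5 without genotype as a term; the cause was not tested. Leaving out 1 array at a time left room for 1 factor only. These fits gave 0 to 25 genes for genotype and 0 to 704 for age, where the 1-factor fits of all 4 arrays gave 0 and 5. The 25 came without the Mkx-KO array of 10 weeks (1 higher, 24 lower) and the 704 without the WT array of 4 weeks (618 higher, 86 lower). In these fits of 3 arrays the lone array of a group is assumed to vary like the others, and genotype and age are not separated.

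Of 1224 list values under alternatives, 1190 kept their call, 23 lost it and 11 gained it. Centring, the deposited scaled values and members at bounds each kept 136 of 136. Centring and the deposited values shift all genes of an array alike, so they could not change a call, and few members were at a bound. The lists on the same side for genotype at both ages fell from 4 to 2 with no background filter, which left interferon genes and small leucine-rich proteoglycans; the cause was not tested. Genotype calls lost at 4 weeks were small leucine-rich proteoglycans (quantile), B cells (normexp, no filter), T cells and adipocytes (no filter), and osteoblasts and Schwann cells (probe mean). Those lost at 10 weeks were T cells, mitochondria and endothelium (normexp) and osteoblasts (quantile). For age in WT the T cell call was lost (probe mean). Of 3305 values of named genes, 2876 stayed at least 2-fold apart or, if under 2-fold, moved by no more than their technical error; 142 fell under 2-fold, 46 came to exceed it and 241 moved by more than the error. Signal over background limits the dim genes: the lowest level called well above background lay between -4.90 and -4.53. The slide as a block was not run, since there was 1 slide.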

Other observations

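The lists of olfactory, forebrain and other genes used here were chosen only after the values were seen, and no explanation was tested.

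Forebrain inhibitory neuron genes ranked the arrays differently from nasal genes. Their median for age was -2.01 in WT and 3.0 in Mkx-KO, or 1.85 in Mkx-KO with 6 members at their bounds. For genotype it was 0.94 at 10 weeks, with 8 of 16 at least 2-fold higher, and -3.82 at 4 weeks. With normexp these 4 medians over all members shrank to -0.96, 0.85, 0.58 and -1.29. Over the 10 members well above background on both arrays, the median was 0.77 for age in Mkx-KO and -0.66 for genotype at 4 weeks. The regulators Dlx1, Dlx2, Dlx5, Dlx6 and Lhx6 are among these 10. The GABA transporter gene Slc32a1 and the synaptic gene Syt1, named after their values were seen, stood at 1.1 and 1.91 in WT at 4 weeks, at -0.14 and 1.03 in Mkx-KO at 10 weeks, and at -2.29 and -0.10 in WT at 10 weeks. The regulators Dlx1, Dlx2 and Lhx6, also named afterwards, differed by less than 0.5 between any of the compared arrays but for Dlx2 for age in Mkx-KO (-0.53). Other regulators of the list differed more. For age in Mkx-KO, Dlx5 differed by -0.55 and Dlx6 by -0.65, and for age in WT Dlx6 differed by -0.58. Sp8 stood at -1.20 in WT at 4 weeks and was not well above background in Mkx-KO at 4 weeks. Of the 16 genes, 1 (Dlx5) is also in the osteoblast list.

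Ciliated cell genes were higher at 10 weeks, with a median of 1.5 in WT and 3.29 in Mkx-KO, or 1.34 and 1.73 with members at their bounds and 0.52 and 0.91 with normexp. Of the 11 Mup genes on the array, 11 were well above background on each of the other arrays and 2 on the Mkx-KO array of 4 weeks. Of 13 Bpif genes the numbers were 12 and 6. Of 1080 Olfr genes, 187 were well above background in WT and 155 in Mkx-KO at 10 weeks, and 134 and 116 at 4 weeks.

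The Mkx-KO array of 4 weeks stood alone more often than the others. Of 15504 genes, 295 were at least 2-fold below all other arrays there, against 34 in WT and 16 in Mkx-KO at 10 weeks and 3 in WT at 4 weeks. Genes at least 2-fold above all others numbered 37 there, 89 in WT and 22 in Mkx-KO at 10 weeks, and 87 in WT at 4 weeks.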
